A study of Drosophila melanogaster with 13 samples.

How the data were processed

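Messenger RNA of adult Drosophila melanogaster heads was sequenced in 13 libraries made from 12 RNA samples. The samples cover 2 larval diets, 2 sexes and 3 strains, with 1 RNA sample in each combination, and each sample was a pool of 70 to 80 heads taken 2 to 6 h after eclosion. The strains SD2, SD3 and SD6 are isofemale lines, each descended from 1 wild-caught female. Larvae grew at 25 °C under 12 h of light and 12 h of dark, 40 to a vial and 10 vials for each strain and diet, on food with a protein to carbohydrate ratio of 0.43 (HPS, high protein and low sugar) or 0.1 (LPS, low protein and high sugar). Males and females of a strain and diet came out of the same set of vials. The replicate numbers 2, 3 and 6 in the sample titles are the strain numbers.

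The deposited values are counts of reads per gene, whole numbers that were not normalized. Per the labels' protocols, poly(A) RNA was taken from 100 ng of total RNA with a stranded kit, 20 pg of spike-in RNA was added, and single-end reads of 75 bp were produced. The submitters' processing notes name CASAVA 1.8.2, bcl2fastq 1.8, TopHat2 2.1.0 and HTSeq 0.6.1p1. The deposited file names mark the counts as made from uniquely mapped reads on the reverse strand, so reads shared by near-identical genes are left out and sense and antisense genes are counted apart. The genome build and annotation behind the counts are not given in the sources used here. Gene symbols and chromosome arms were taken from the Ensembl annotation of the BDGP6 assembly through the FlyBase identifiers, and 17155 of 17370 counted genes had a symbol there. The 96 spike-in entries and the 5 summary entries that name no gene stayed out of library sizes and tests. Reads assigned to no gene made up 2.93% to 4.96% of the reads in the 11 libraries of 1 sequencing run and 10.4% to 14.9% in the 2 libraries of the other, and ambiguous reads made up 2.65% to 3.91% over all 13.

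The male LPS SD2 RNA was sequenced as 2 libraries in different runs. Over 10118 genes with at least 10 reads in sum their counts differed by more than sampling noise, with a chi-square of 13.0 per degree of freedom, and the SD of their log2 difference was 0.288 against a median of 0.676 over the other pairs of libraries. Among the other pairs 1 was lower, the male HPS SD6 library and the library labelled male LPS SD3, at 0.286. The 2 male LPS SD2 libraries were added together and counted as 1 sample, as fixed before the data were examined. The second of these libraries and the male HPS SD2 library form the smaller run, so the run is confined to SD2 males.

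Depth ran from 7.84 M to 25.3 M gene reads per library, and the summed male LPS SD2 sample held 27.5 M. In each library 11448 to 12549 genes had at least 1 read. A count of 3 reads, taken as the floor below which a gene is not called detected, corresponds to 0.119 to 0.382 counts per M unscaled gene reads. Floors cover counting error only.

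Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter over the 4 groups of diet and sex at a minimum count of 10, and the quasi-likelihood F-test. This left 10026 genes. Diet, sex and strain were fitted together, with strain as a fixed block and 7 residual degrees of freedom, and an adjusted p below 0.05 by the Benjamini-Hochberg method was the threshold. Diet within each sex and the diet by sex interaction came from a fit with the 4 groups and strain, and the interactions of strain with diet and with sex from fits holding those terms. Values per gene are log2 fold changes with their standard errors (SE), and levels are counts per M gene reads, with library sizes scaled by the TMM factors (CPM), as mean ± SD. Each RNA pool is 1 replicate, and males and females from the same vials count as separate samples, so p-values measure only the spread between these pooled samples.

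The pairing by strain was checked as the correlation of each sample's deviations from its group mean. Samples of the same number correlated at 0.617 to 0.809 where neither was the library labelled male LPS SD3 nor the library labelled male LPS SD6. Pairs of these 2 libraries with samples of their own number correlated at −0.363 to −0.269, and each of them correlated at 0.641 to 0.767 with samples of the other's number. Numbers pair the samples by design, since a number is a line, so strain stayed as the block. The main counts are given as labelled, and also without these 2 libraries and with their strain labels exchanged, alternatives that were chosen after seeing the data. Without the 2 libraries 10373 genes were tested in 10 samples.

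A total of 44 gene lists were fixed before the data were examined. They cover larval serum proteins and larval fat body, adult fat body, haemocytes, muscle, glia, gut enzymes, testis, accessory gland, ovary and germ line, insulin, FOXO and TOR signalling, the sugar-sensing Mondo-Mlx programme, fatty acid and triglyceride synthesis, lipolysis and beta-oxidation, glycolysis, trehalose and glycogen metabolism, amylases and maltases, amino acid metabolism, antimicrobial peptides, heat shock, folding in the endoplasmic reticulum, detoxification, oxidative stress defence, synaptic vesicle and active zone, transmitter synthesis and transport, neuropeptides, their receptors together with transmitter receptors, ion channels of excitability, phototransduction, eye pigment, olfaction and taste, circadian clock, cuticle proteins, cuticle tanning and chitin, ecdysone response, juvenile hormone, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, proteasome, ribosome biogenesis, cell cycle and DNA replication, sex determination and dosage compensation, genes known to be sex-biased in adult heads, and Y-linked genes. Of 1284 listed names 1240 were found among the counted genes. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The main list result is camera at the preset correlation, adjusted over the lists.

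The genes named were chosen by a rule written before the data were examined. Among genes past the threshold with mean log2 CPM above 0, the same sign in all 6 pairs of samples and a symbol beyond a CG or CR number, it took the 8 largest rises and the 8 largest falls. In each list it took up to 4 members past the threshold with the smallest p, or the member with the smallest p as a value where none passed. For strain and the interactions it took the 6 smallest p. It fixed in advance roX1, roX2, Yp1, Yp2, Yp3, msl-2, Sxl, tra, dsx, fru and the Y-linked list for sex, and Ilp2, Ilp3, Ilp5, Ilp6, InR, Thor, bmm, FASN1, sug, ple, Ddc and Pdf for diet. At most 2 rises and 2 falls of number-only genes were named for each comparison. The same rule was applied to the fits without the 2 libraries whose strain is in doubt.

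The fits were tested on simulated counts of 9999 genes drawn from the real samples' means, of which 200 were changed in each comparison. The changed genes were taken from those with a mean log2 CPM above 1, so the shares called below do not cover genes at lower levels. The 2 libraries of doubtful strain were simulated with their strain labels exchanged, using the spread between samples under that exchange. The labels called right here are therefore the exchanged ones. The common dispersion was 0.00711 with exchanged labels and 0.0205 as labelled. With the strain labels right, 99% of the 2-fold and 100% of the 4-fold changes by diet were called, and 2.83% of the 212 calls were unchanged genes; for sex 100% of both were called. For the diet by sex interaction 87% and 100% were called, for diet by strain 56% and 94%, and for sex by strain 57% and 94%. The same simulated data were also fitted with the labels as given, which are wrong for 2 simulated libraries. Then 93% and 100% were called by diet and 91% and 99% by sex. It was 53% and 87% for diet by sex, and 0% for both interactions with strain. In a simulation of the diet lists without an effect 0 of 40 lists were called by camera, and a muscle list moved 1.25-fold was called at either correlation. In the latter simulation camera at the preset correlation called 2 lists, 1 of them not moved. Simulated genes were drawn independently of each other. These list simulations therefore cannot show how often camera calls lists whose genes vary together without an effect.

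The alternatives fixed in advance were the fit without the replicate block, a block by strain and sex (or strain and diet), limma-voom with strain as a random effect, male and female counts summed within strain and diet, RLE and upper quartile normalization, DESeq2 1.42.0, no filter on low counts and a stricter one at a mean log2 CPM of 1, robust dispersion, either library of the male LPS SD2 RNA alone, all 13 libraries with run as a covariate, the fit without SD2 males, and leaving out each sample or each strain. Spike-in counts were not used for scaling. Ratios between storage protein transcripts, added later, are each member's log2 CPM minus the mean of the other members in the same sample, fitted by diet, sex and strain and tested by a t-test adjusted over the 6 members.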

Results

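Read counts were obtained for the heads of flies that had left the pupal case 2 to 6 h earlier. The question is how the food of the larva bears on the head, and with it the nervous system, of the adult. The 12 RNA samples comprise 1 pool of heads for each diet (HPS, rich in protein, or LPS, rich in sugar), sex and strain (SD2, SD3 or SD6). This gives 6 samples per diet, 6 per sex, 4 per strain and 3 per group of diet and sex. Depth lay between 7.84 M and 27.5 M gene reads per sample. Differences are LPS against HPS or male against female, as log2 fold changes ± SE from edgeR's quasi-likelihood test unless another source is named.

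Strain set the largest differences between samples. The first principal component of log2 CPM, with 33.7% of the variance, parted SD2 from the other strains. The second, with 29.8%, parted SD3 from SD6. On it the library labelled male LPS SD3 lay with SD6 and the library labelled male LPS SD6 lay with SD3. On 397 genes that separate SD3 (set to 0) from SD6 (set to 1) in the remaining samples, the library labelled male LPS SD3 stood at 1.01 and the library labelled male LPS SD6 at 0.027. The other SD3 samples lay between −0.029 and 0.014 and the other SD6 samples between 0.954 and 1.06. Obp99a, an odorant-binding protein, averaged 1.57 CPM in SD3 and 132 CPM in SD6. It was at 140 CPM in the library labelled male LPS SD3 and 0.925 CPM in the library labelled male LPS SD6. The G protein-coupled receptor gene mth ran the other way, with 49.7 CPM in SD3, 1.71 CPM in SD6, and 1.28 and 53.5 CPM in the same 2 libraries. Obp99a and mth were chosen here after their values were seen. An exchange between these 2 libraries alone would change the strain block and leave sex and diet labels as they are, since both are labelled male LPS. Whether the diet labels hold was not tested. The main counts are therefore given as labelled and then without these 2 libraries or with their strain labels exchanged.

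**Figure D1:**
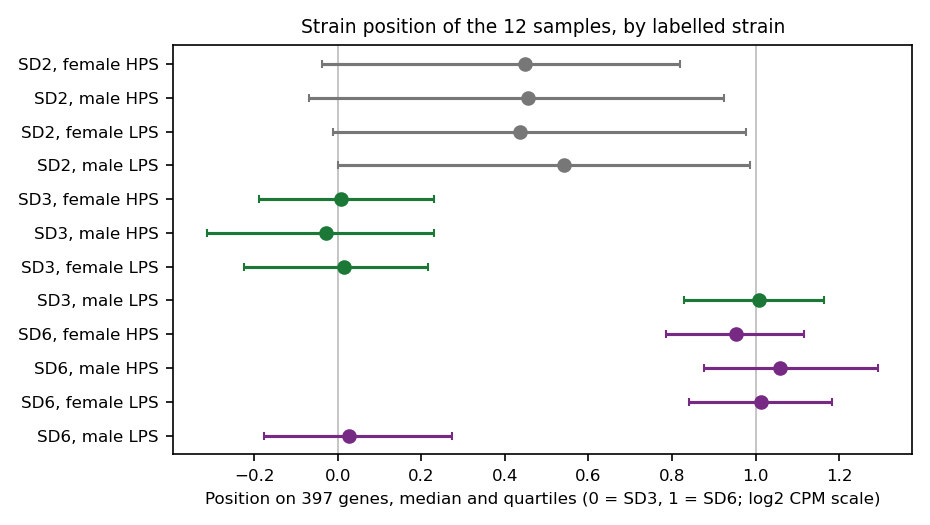
Position of each of the 12 samples between SD3 (0) and SD6 (1) on 397 genes that part these strains, on the log2 CPM scale. Points are medians over the genes, bars run from the lower to the upper quartile, and color is the labelled strain. The library labelled SD3 male LPS sits at 1.01 and the library labelled SD6 male LPS at 0.027.

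Transcripts of the larval storage proteins were lower in heads of flies raised on the sugar-rich diet. Lsp1alpha (FBgn0002562, chromosome arm X), a subunit of the hexamerin that larval fat body lays down for metamorphosis, fell by 2.32 ± 0.30 on the log2 scale. Its level went from 9.90 ± 8.72 CPM on HPS to 1.88 ± 1.73 CPM on LPS (mean ± SD, n = 6 each), and it was lower in all 6 pairs of samples (edgeR adjusted p = 0.0204). All 6 tested members of the larval serum protein and larval fat body list were negative, with a median of −1.54. As labelled 1 passed the threshold over all genes, and 3 did when adjusted over the list alone. Without the 2 libraries of doubtful strain all 6 fell (n = 4 on LPS and 6 on HPS). Lsp1beta changed by −1.04 ± 0.09, Lsp2 by −1.14 ± 0.15 and Lsp1alpha by −2.21 ± 0.19. Fbp1, which encodes the receptor that takes the storage proteins up, changed by −2.73 ± 0.38 and Fbp2 by −2.66 ± 0.34. Lsp1gamma had the smallest fall of the 6, at −0.965, and it did not fall in every pair. In SD2 males it had 32 reads in the HPS library (10.2 M gene reads). It had 58 and 41 in the LPS libraries (15.9 M and 11.7 M), so it was not lower there. In females of each strain it was lower on LPS per M gene reads. Camera put the list apart as labelled (adjusted p = 5.96e-09; adjusted p = 0.0977 with an estimated correlation). With an estimated correlation it was 0.0254 without the 2 libraries and 0.00403 with their labels exchanged.

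**Figure D2:**
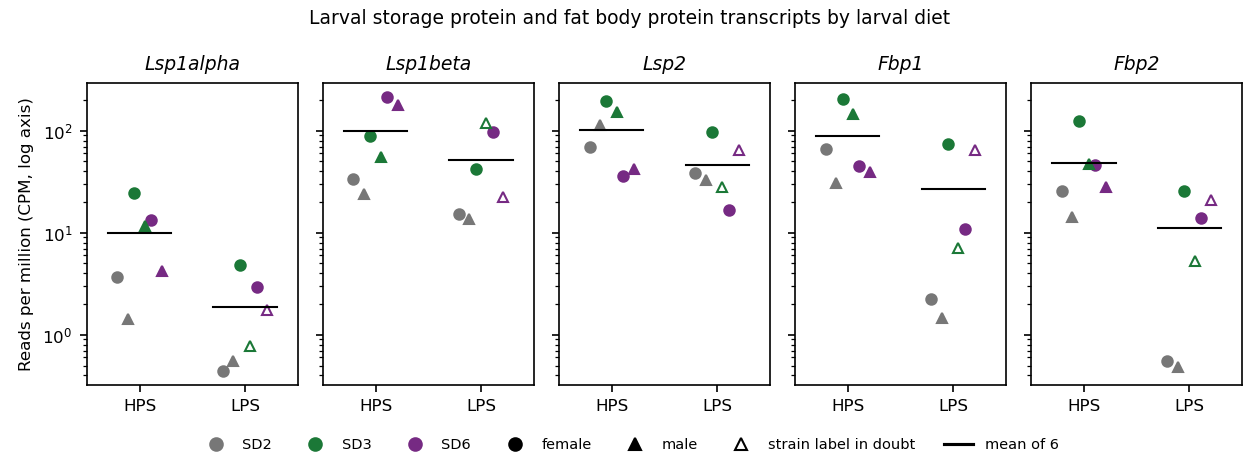
CPM (log axis) of 5 larval fat body transcripts in the 12 samples by larval diet. Lsp1gamma is not drawn. Circles are females, triangles males, colors the labelled strains, open triangles the 2 male LPS libraries whose strain label is in doubt, and lines the means of 6 samples. Mean Lsp1alpha was 9.90 CPM on HPS and 1.88 CPM on LPS.

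Of 10026 genes tested by diet as labelled 10 passed the threshold, 2 higher and 8 lower on LPS, Lsp1alpha among them. Further falls were those of Sardh (FBgn0034276, chromosome arm 2R), the mitochondrial sarcosine dehydrogenase (−0.88 ± 0.11, adjusted p = 0.0204), and Sodh1 (FBgn0024289, chromosome arm 3R), a sorbitol dehydrogenase (−0.62 ± 0.08, adjusted p = 0.0204). Number-only falls were CG8665 (−1.76 ± 0.25) and CG34138 (−1.02 ± 0.13). Both rises were number-only genes, CG8654 (0.81 ± 0.11, adjusted p = 0.028) and CG7227 (0.62 ± 0.09, adjusted p = 0.0304). Each of these 6 kept its sign in all 6 pairs. Leaving out the 2 libraries gave 147 genes, 33 higher and 114 lower, and exchanged labels gave 170, 49 higher and 121 lower. All 10 were among both, and 102 genes were shared by the latter sets. The fit without the replicate block by strain called 0 genes, as did the fits without the SD2 males and without any 1 of 5 single samples, and DESeq2 called 111. Over 36 alternatives Lsp1alpha passed in 21, with an adjusted p from 2.17e-29 to 0.664 and log2 values from −2.62 to −1.96. Males and females of a strain and diet shared vials, and with their counts summed (n = 3 per diet) 0 genes passed as labelled, with Lsp1alpha at −2.31 ± 0.22 (adjusted p = 0.129), and 120 with exchanged labels. Why the call ended in the summed samples was not tested. With a block by strain and sex 3 genes passed, Sardh and CG8654 among them, and Lsp1alpha was at −2.38 ± 0.31 (adjusted p = 0.0542).

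In the fit without the 2 libraries (n = 4 on LPS and 6 on HPS) further genes passed by diet. As labelled none of the genes of this paragraph passed, from Obp99b (−1.35 ± 0.21, adjusted p = 0.0574) to lush (−0.29 ± 0.38, adjusted p = 0.896). Dgat2 (FBgn0033215, chromosome arm 2R), which catalyses the last step of triglyceride synthesis, rose by 1.04 ± 0.12, while the list of fatty acid and triglyceride synthesis that holds it was not called. The peroxisomal acyl-CoA oxidase genes Acox57D-d and Acox57D-p rose by 0.64 ± 0.07 and 0.43 ± 0.07, and AkhR, the receptor of adipokinetic hormone, by 0.50 ± 0.09. The sugar-induced transcription factor gene sugarbabe (sug) rose by 0.88 ± 0.19 and the cytochrome P450 gene Cyp4e3 by 2.15 ± 0.21, from 59.0 ± 24.2 CPM on HPS to 301 ± 222 CPM on LPS over all samples. The ornithine decarboxylase gene Odc1 (0.63 ± 0.14), Sirup (0.55 ± 0.11), the metallothionein gene MtnA (0.62 ± 0.11), the antiviral gene Vago (0.48 ± 0.11) and the dopamine receptor gene Dop1R1 (0.34 ± 0.07) rose as well. In the same fit the odorant-binding protein gene Obp99b fell by 1.51 ± 0.12 on the log2 scale. The metallothionein gene MtnD fell by 2.14 ± 0.34 at a low level (1.65 CPM on HPS and 0.383 CPM on LPS over all samples). Os-C changed by −1.04 ± 0.13, and resilin, an elastic cuticle protein, by −1.23 ± 0.13. The small heat shock gene Hsp23 (−0.66 ± 0.11), the lactate dehydrogenase gene Ldh (−0.53 ± 0.11), and cnc, the fly Nrf2 (−0.25 ± 0.06), fell too. So did the attacin gene AttA (−1.64 ± 0.28), the amylase gene Amy-p (−1.60 ± 0.36), Obp99d (−0.55 ± 0.12) and lush (−0.52 ± 0.11). Over the alternatives tried, the adjusted p of Dgat2 ran from 0.000329 to 0.999, that of Cyp4e3 from 5.33e-15 to 0.999 and that of Obp99b from 8.62e-22 to 0.999. With exchanged labels AttA, Obp99d and lush did not pass (adjusted p = 0.0588, 0.458 and 0.117; over the alternatives 0.00548 to 0.999, 0.046 to 1 and 0.0392 to 1). Their log2 values ran from −1.86 to −0.37 for AttA, from −0.55 to −0.077 for Obp99d and from −0.82 to 0.028, which changes sign, for lush. AttA and Amy-p have near-identical neighbours, and only reads unique to each were counted.

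Camera set 14 of the 40 tested lists apart by diet, 9 lower and 5 higher on LPS, and 0 of them held with an estimated correlation. With the 2 libraries left out 18 of 42 were called and with exchanged labels 17, and the larval serum protein list alone held in each. The proteasome, which degrades tagged proteins, had all 33 members negative, with a median of −0.15 (adjusted p = 1.67e-18; adjusted p = 0.289 with an estimated correlation). None of them passed over all genes and 7 did when adjusted over the list alone. In the fit without the 2 libraries these counts were 2 (Rpn2, −0.39 ± 0.08, and Rpt6R, −0.61 ± 0.08) and 23. Muscle genes were negative in 19 of 21 (median −0.15, adjusted p = 0.000202; adjusted p = 0.648 with an estimated correlation). When the 2 libraries were left out 5 fell, among them the troponin genes up (−0.38 ± 0.08), wupA (−0.33 ± 0.06) and TpnC73F (−0.70 ± 0.12) and the actin gene Act87E (−0.56 ± 0.12). As labelled none of these named genes passed, with an edgeR adjusted p from 0.695 for up to 0.894 for TpnC73F. Over 36 alternatives Act87E passed in 3 and each of the troponin genes in 2. The log2 values of TpnC73F ran from −0.88 to −0.04 and those of Act87E from −0.64 to −0.13. The called lists with positive medians included 3 of the nervous system. Neuropeptides were positive in 26 of 31 (median 0.15, adjusted p = 0.000127; adjusted p = 0.289 with an estimated correlation). In the same order of values, synaptic vesicle and active zone genes were positive in 19 of 21 (0.10, 0.00306 and 0.899) and receptors of transmitters and neuropeptides in 28 of 36 (0.11, 0.00488 and 0.899). Lipolysis and beta-oxidation genes were positive in 15 of 16 (0.13, 0.000127 and 0.137) and mitochondrial ribosomal proteins in 53 of 70 (0.09, 0.00156 and 0.951). None of the lipolysis genes passed over all genes and 3 rose when adjusted over the list alone, against 3 and 5 without the 2 libraries.

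The remaining called lists were lower on LPS, again given as median, adjusted p and adjusted p with an estimated correlation. They were glycolysis (−0.09, 0.00488 and 0.467), amylases and maltases (−0.11, 0.00897 and 0.203), eye pigment (−0.11, 0.0157 and 0.521), cuticle proteins (−0.07, 0.0171 and 0.349), heat shock (−0.07, 0.0199 and 0.76) and trehalose and glycogen metabolism (−0.13, 0.0423 and 0.349). None of their members passed over all genes. Adjusted over the list alone 1 fell in glycolysis (Ldh), 1 in eye pigment, 2 in heat shock and 2 in cuticle proteins, where 1 rose. The calls for the storage protein, proteasome, lipolysis and amylase lists were also made by fry. The omission of the 2 libraries ended the call of glycolysis (adjusted p = 0.071). It added adult fat body (median 0.18, adjusted p = 0.0305), detoxification (0.07 and 0.0326), glia (0.07 and 0.0328), cuticle tanning (−0.10 and 0.0146) and gut enzymes (−1.07 and 0.00342). None of these 5 held with an estimated correlation in that fit (adjusted p = 0.492, 0.576, 0.359, 0.702 and 0.239 with an estimated correlation).

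**Figure D3:**
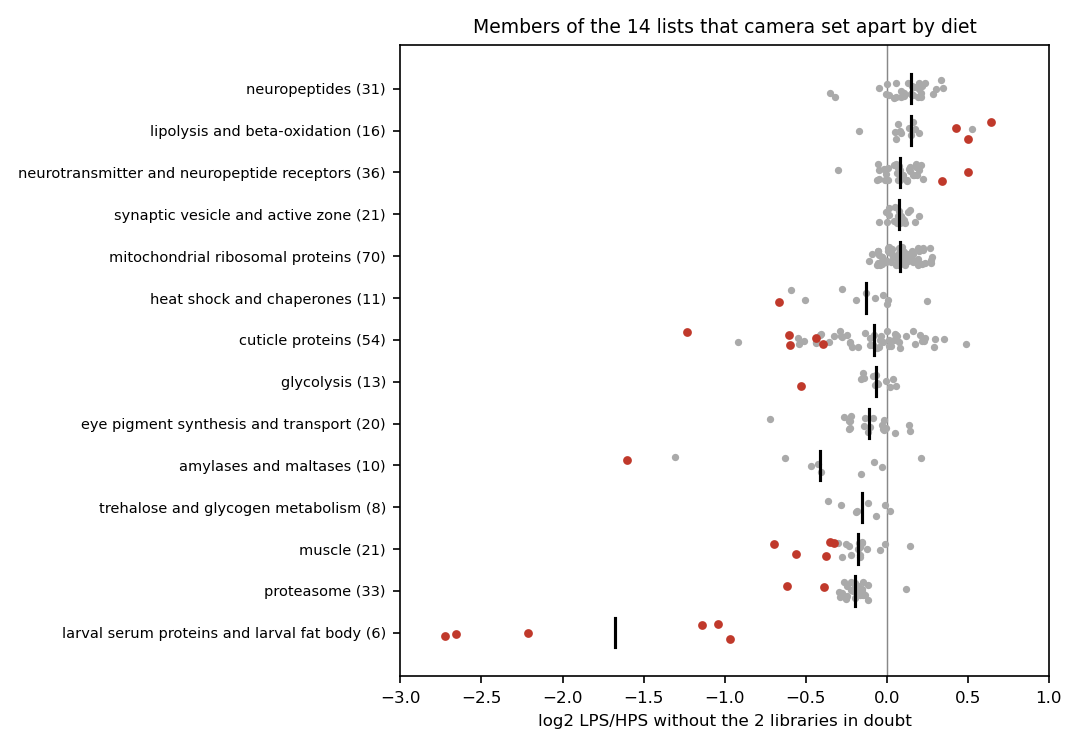
Log2 difference between diets of each member of the 14 lists that camera set apart by diet, from the fit without the 2 libraries whose strain label is in doubt. Grey points are members not past the threshold, red points members with an edgeR adjusted p below 0.05, black bars the list medians, and the number of members tested as labelled is in parentheses. The larval serum protein list has a median of −1.67 and all 6 members past the threshold.

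The lists that camera did not set apart by diet as labelled included adult fat body (median 0.19, adjusted p = 0.0607), cuticle tanning and chitin (−0.08 and 0.0622) and amino acid metabolism (−0.09 and 0.071). Further medians were −0.02 for cytosolic ribosomal proteins (adjusted p = 0.255), 0.05 for ion channels (0.273), −0.03 for ribosome biogenesis (0.394) and 0.07 for detoxification (0.467). They were 0.04 for transmitter synthesis and transport (0.537), 0.05 for fatty acid and triglyceride synthesis (0.553), −0.04 for insulin, FOXO and TOR signalling (0.553), 0.04 for glia (0.553) and 0.03 for oxidative phosphorylation (0.61). The Mondo-Mlx list had a median of −0.06 (0.614), endoplasmic reticulum folding −0.009 (0.758), haemocytes −0.02 (0.83), the cell cycle 0.04 (0.868), the circadian clock 0.01 (0.933), ovary and germ line 0.11 (0.945) and phototransduction 0.009 (0.986). It was 0.06 for sex-biased head genes (0.704), 0.05 for juvenile hormone (0.735), 0.02 for oxidative stress defence (0.807) and 0.04 for olfaction and taste (0.945). The ecdysone response had 0.008 (0.992), antimicrobial peptides 0.03 (0.986) and sex determination −0.006 (0.986). Median, mean and camera's direction differed in sign for sex-biased head genes, juvenile hormone, oxidative stress, haemocytes, cell cycle, olfaction, ecdysone, Mondo-Mlx and sex determination. Adjusted over the list alone, 2 genes rose in fatty acid synthesis and 2 in haemocytes, and 1 rose in detoxification. Likewise 2 rose and 2 fell in Mondo-Mlx, 1 rose and 3 fell in amino acid metabolism, and 1 fell in each of juvenile hormone, olfaction and sex-biased head genes. Over all genes only Sardh, of amino acid metabolism, passed in these lists. The gut enzyme and testis lists had 4 and 3 tested members, with medians of −0.67 and −0.29, and the accessory gland and Y-linked lists had 0.

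The insulin-like peptide genes of the brain did not pass the threshold by diet. Ilp2 was at 0.23 ± 0.08, Ilp3 at −0.12 ± 0.13 and Ilp5 at −0.16 ± 0.12, with Ilp6 of the fat body at 0.13 ± 0.08 and the insulin receptor InR at 0.18 ± 0.08. Thor, the 4E-BP target of FOXO, was at −0.19 ± 0.11, the lipase gene bmm at −0.10 ± 0.07 and the fatty acid synthase gene FASN1 at 0.04 ± 0.11. Of the genes of dopamine synthesis, ple was at −0.14 ± 0.21 and Ddc at −0.17 ± 0.12, and the clock neuropeptide gene Pdf was at 0.18 ± 0.10. Their edgeR adjusted p ran from 0.436 for Ilp2 to 0.956 for FASN1 (n = 6 per diet).

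Within the sexes, the smallest p-values by diet in females belonged to genes already named and a few others. Sardh was at −0.97 ± 0.16, the serine protease homologue SPH93 at −1.50 ± 0.25, and Hsp23 at −0.79 ± 0.14. Obp99b stood at −1.64 ± 0.28, Lsp1alpha at −2.40 ± 0.42 and Mp20, a muscle protein, at −0.66 ± 0.12 (n = 3 per diet). As labelled edgeR called 0 genes in females, with 420 at an unadjusted p below 0.05. DESeq2 called 23 and limma-voom 0. After the 2 libraries, which are both male, were left out, 54 genes passed, 10 higher and 44 lower, and with exchanged labels 28, all of them among the 54. In males Sirup was at 0.79 ± 0.12, the cuticle genes Ccp84Ad and Ccp84Ab at −1.07 ± 0.19 and −0.87 ± 0.17. The eye pigment transporter gene bw was at −0.45 ± 0.08, Sodh1 at −0.61 ± 0.12 and Sf3b5 at 0.68 ± 0.14. EdgeR called 0 genes in males (581 at an unadjusted p below 0.05; DESeq2 19, limma-voom 0) and 12 with exchanged labels. The count without the 2 libraries was 0, but it rests on 1 male LPS sample, which is assumed to vary like the other groups. The difference between the sexes in the diet effect passed for 0 genes in edgeR, DESeq2 and limma-voom (180 at an unadjusted p below 0.05). The smallest p-values were those of the stress gene TotA (1.41 ± 0.30, male against female diet effect), Ccp84Ad (−1.07 ± 0.25), and Sf3b5 (0.79 ± 0.19). Next came Sem1 (0.68 ± 0.17), ND-15 (0.56 ± 0.14) and COX7AL2 (0.77 ± 0.20), all at an edgeR adjusted p of 1.

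Sex labels fitted the transcripts that report sex. The yolk protein genes Yp1 and Yp2, expressed in female fat body, averaged 2107 ± 663 and 1948 ± 554 CPM in females against 3.93 ± 1.59 and 13.5 ± 8.73 CPM in males (n = 6 each). Yp3 differed by −3.43 ± 0.30. The male-specific roX1 RNA of the dosage compensation complex had 9 to 24 reads in each female library and at least 5865 in each male library. roX2 had 0 to 2 reads in each female library and at least 223 in each male library. msl-2, the subunit that limits this complex to males, was higher in males by 0.98 ± 0.07 (adjusted p = 6.66e-05). The Y-linked genes had at most 2 reads in any library. Of the other sex determination genes, fru (−0.36 ± 0.06), dsx (−0.55 ± 0.12) and tra (−0.53 ± 0.12) were lower in males, and Sxl was at −0.32 ± 0.10 (adjusted p = 0.119).

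In all, 305 genes differed between the sexes as labelled, 87 higher and 218 lower in males, and 39 of them by more than 2-fold. The rule for named genes asked for a mean log2 CPM above 0 and the same sign in all 6 pairs. Among genes with a name that met it, the largest male excess after roX1 and roX2 was in brv3. Its level was 3.81 ± 1.38 CPM in males and 0.0391 ± 0.0722 CPM, below the floor, in females. Next came Cyp4d21, the sex-specific cytochrome P450 also known as sxe1 (1.87 ± 0.32). Then followed Cyp4d14 (1.63 ± 0.37), Gcna (1.60 ± 0.23), feo (1.57 ± 0.28) and sxe2 (1.31 ± 0.21). Under the same rule, the largest female excesses after the yolk proteins were in the myoblast fusion gene rost (−1.75 ± 0.22), the mannosyltransferase gene tw (−1.23 ± 0.13), the myosin gene Myo61F (−1.16 ± 0.16), frma (−0.99 ± 0.08) and the cuticle gene Ccp84Aa (−0.89 ± 0.17). Genes called by sex that did not meet the rule, Lsp1alpha among them, are not ranked here. Number-only genes with the largest changes were asRNA:CR45601 (−6.44 ± 0.36) and CG1368 (−3.46 ± 0.22) among the lower ones and asRNA:CR45479 (2.81 ± 0.19) and lncRNA:CR32553 (2.22 ± 0.25) among the higher ones. With the 2 libraries of doubtful strain left out 801 genes passed, 290 higher and 511 lower, 301 of the 305 among them. With exchanged labels 1127 passed, 431 higher and 696 lower, with 303 of the 305. The fit without the replicate block called 153 and the fit without SD2 males 40.

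Called genes were concentrated on the X chromosome. On the X 138 of 1631 tested genes (8.46%) differed by sex, against 163 of 8247 (1.98%) on the autosomes. The odds ratio was 4.58 (95% interval 3.60 to 5.83; Fisher's exact test across genes, two-sided, adjusted over the 18 comparisons of this kind, p = 5.02e-33). It was lower in the other fits, at 3.25 (2.77 to 3.80) without the 2 libraries, with 286 X-linked and 504 autosomal genes, and at 2.91 (2.53 to 3.35) with exchanged labels, with 366 and 745. Both directions took part, with 47 higher and 91 lower in males on the X, and the median log2 difference of all tested genes was 0.0046 on the X and 0.014 on the autosomes. By diet 1 X-linked gene, Lsp1alpha, and 8 autosomal genes passed (Fisher's exact adjusted p = 1). Genes are not independent replicates, so these tests describe the called set.

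The lists of muscle, adult fat body, haemocytes and ribosome biogenesis had negative medians in male heads, with a part of their members past the threshold. In the muscle list 7 of 21 members were lower (12 when adjusted over the list alone, where 1 was higher; median −0.39). The camera adjusted p was 1.90e-08, and adjusted p = 0.273 with an estimated correlation. Among the 7 were projectin bt (−0.79 ± 0.14), TpnC41C (−0.58 ± 0.09), myosin heavy chain Mhc (−0.55 ± 0.09) and paramyosin Prm (−0.49 ± 0.08). In the haemocyte list 6 of 18 were lower (10 when adjusted over the list alone; median −0.34, adjusted p = 7.05e-08; adjusted p = 0.0261 with an estimated correlation). Hemolectin Hml was at −0.77 ± 0.11, papilin Ppn at −0.60 ± 0.10, Glt at −0.50 ± 0.07 and the collagen gene Col4a1 at −0.40 ± 0.06. The adult fat body list (median −0.42, adjusted p = 5.49e-08; adjusted p = 0.0261 with an estimated correlation) had 4 of 12 lower. These were the 3 yolk protein genes and the lipid transfer particle gene Apoltp (−0.48 ± 0.07). When adjusted over the list alone 5 were lower and 1 higher. Of 25 ribosome biogenesis genes 5 were lower (14 lower and 1 higher when adjusted over the list alone; median −0.25, adjusted p = 1.20e-07; adjusted p = 0.273 with an estimated correlation). They included nop5 (−0.70 ± 0.11), Nop60B (−0.67 ± 0.10), Nop56 (−0.52 ± 0.08) and the RNA polymerase I subunit Polr1A (−0.36 ± 0.06).

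Nervous system and photoreceptor lists had positive medians in males, with few members past the threshold over all genes. All 20 genes of transmitter synthesis and transport were positive (median 0.18, adjusted p = 9.37e-06; adjusted p = 0.293 with an estimated correlation), with 0 past the threshold over all genes and 8 higher when adjusted over the list alone. Among 31 neuropeptide genes 3 were higher, 7 when adjusted over the list alone: AstC (0.38 ± 0.05), Dh31 (0.40 ± 0.06) and Orcokinin (0.35 ± 0.08) (median 0.15, adjusted p = 7.64e-05; adjusted p = 0.229 with an estimated correlation). Phototransduction genes were positive in 26 of 28 (median 0.11, adjusted p = 7.64e-05; adjusted p = 0.273 with an estimated correlation), and the ultraviolet opsin gene Rh4 was higher (0.41 ± 0.08). Synaptic vesicle genes were positive in 20 of 21 (0.14, 0.000866 and 0.559 in the same order), receptors in 31 of 36 (0.09, 0.00798 and 0.576) and sex determination genes in 9 of 14 (0.07, 0.0393 and 0.273).

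Of the 40 lists 19 were called by sex, 6 higher and 13 lower in males, against 20 of 42 without the 2 libraries and 22 of 40 with exchanged labels. As labelled adult fat body, haemocytes and sex-biased head genes held with an estimated correlation. Leaving out the 2 libraries, 0 lists did (camera adjusted p with an estimated correlation 0.0652, 0.0652 and 0.123 for these 3), and with exchanged labels the same 3 did (0.018, 0.018 and 0.0245). The other lower lists, as median, adjusted p and adjusted p with an estimated correlation, were sex-biased head genes (−0.45, 2.41e-05 and 0.0261), cytosolic ribosomal proteins (−0.11, 1.36e-07 and 0.559), oxidative phosphorylation (−0.08, 4.20e-05 and 0.57) and cuticle proteins (−0.18, 0.000172 and 0.157). They also included lipolysis and beta-oxidation (−0.13, 0.000172 and 0.0894), antimicrobial peptides (−0.31, 0.00356 and 0.57), cell cycle (−0.15, 0.00845 and 0.232), larval serum proteins (−0.37, 0.0121 and 0.273) and glycolysis (−0.10, 0.0304 and 0.465). In them the cuticle genes Cpr64Aa (−0.89 ± 0.11) and Cpr11A (−0.61 ± 0.08), the replication genes Mcm7 (−0.56 ± 0.10) and RnrS (−0.47 ± 0.10), RpLP0-like (−0.32 ± 0.07), PGRP-SB1 (−0.46 ± 0.11) and Lsp1alpha (−1.26 ± 0.30) passed over all genes. Over all genes against adjusted over the list alone, the lower members numbered 3 and 5 for sex-biased head genes (where 1 and 2 were higher), 5 and 10 for cuticle proteins and 0 and 5 for lipolysis. They numbered 1 and 2 for antimicrobial peptides, 2 and 2 for the cell cycle, 1 and 1 for larval serum proteins, 1 and 0 for cytosolic ribosomal proteins, and 0 and 0 for oxidative phosphorylation and glycolysis. Lists that include the yolk protein genes, adult fat body and sex-biased head genes, share those members.

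**Figure D4:**
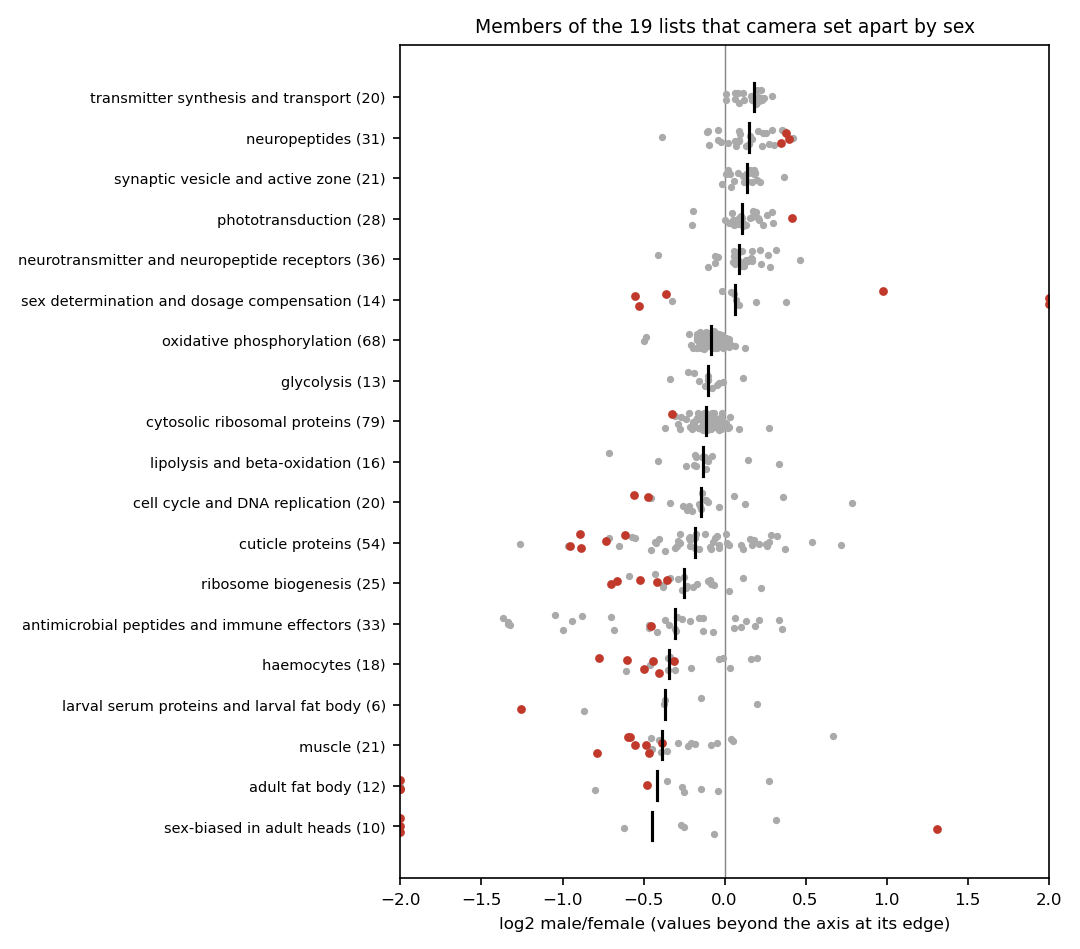
Log2 difference between males and females of each member of the 19 lists that camera set apart by sex, all samples as labelled. Grey points are members not past the threshold, red points members with an edgeR adjusted p below 0.05, black bars the list medians, and the number of members tested is in parentheses; values beyond −2 or 2 are drawn at the edge. The muscle list has a median of −0.39 and the transmitter list of 0.18.

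The lists not called by sex held single genes that passed. These were the eye pigment genes w (0.58 ± 0.12) and car (0.37 ± 0.06), t, which encodes an enzyme of pigment and histamine recycling (0.48 ± 0.08), and the growth factor gene Idgf4 (−0.52 ± 0.09). They were also Ilp5 (−0.57 ± 0.12), Obp56d (−0.60 ± 0.13), Odc1 (−0.61 ± 0.14), Ahcy (−0.41 ± 0.10), and GstE3 (−0.37 ± 0.09). In the proteasome list 4 subunits passed, Rpt3 (−0.38 ± 0.06), Rpt4 (−0.38 ± 0.07), Rpt6 (−0.36 ± 0.07) and Prosalpha4 (−0.31 ± 0.06). Medians and adjusted p-values were −0.08 and 0.0635 for Mondo-Mlx, 0.09 and 0.0739 for glia, −0.16 and 0.0847 for trehalose and glycogen, and 0.07 and 0.162 for ecdysone. They were −0.02 and 0.208 for detoxification, 0.06 and 0.22 for ion channels, −0.07 and 0.223 for juvenile hormone, and −0.07 and 0.229 for mitochondrial ribosomal proteins. They were −0.06 and 0.275 for oxidative stress, 0.04 and 0.321 for eye pigment, 0.001 and 0.321 for olfaction, and −0.07 and 0.386 for endoplasmic reticulum folding. The clock had 0.05 and 0.386, insulin signalling 0.06 and 0.386, amylases 0.24 and 0.386, and cuticle tanning 0.01 and 0.4. Fatty acid synthesis had 0.004 and 0.639, heat shock −0.005 and 0.639, amino acid metabolism 0.02 and 0.639, ovary and germ line 0.11 and 0.896, and the proteasome 0.04 and 0.987. Median, mean and test differed in sign for juvenile hormone, olfaction, cuticle tanning, fatty acid synthesis, amino acid metabolism and the proteasome. The gut enzyme list had 4 tested members with a median of 0.46 and the testis list 3 with 0.15.

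Between strains 922 genes differed as labelled. Here SD3 and SD6 each include 1 of the 2 libraries of doubtful strain, as labelled. The ranking therefore favours genes that part SD2 from both others over genes that part SD3 from SD6. Of the 6 genes with the smallest p-values 4 were close to absent in SD2 or in both other strains. Kaz1-ORFB had 0.015 ± 0.030 CPM in SD2, which is below the floor, 28.0 ± 2.75 CPM in SD3 and 35.9 ± 5.70 CPM in SD6 (n = 4 each). In the same order sordd2 had 0.082 ± 0.070, 73.6 ± 9.24 and 68.1 ± 21.0 CPM, and Obp57a, an odorant-binding protein, 0.257 ± 0.201, 15.7 ± 1.66 and 17.1 ± 1.28 CPM. The cell cycle gene fzy went the other way, with 68.3 ± 3.12 CPM in SD2, 0.484 ± 0.342 in SD3 and 0.281 ± 0.221 in SD6. Cyp6g1 (FBgn0025454, chromosome arm 2R), a cytochrome P450 known for insecticide resistance, stood at 18.9 ± 0.978 CPM in SD2 against 816 ± 204 in SD3 and 749 ± 98.8 in SD6, and be at 12.1 ± 0.999, 40.4 ± 1.39 and 38.1 ± 1.57 CPM. SD3 differed from SD2 in 984 genes (616 higher) and SD6 from SD2 in 1004 (613 higher) as labelled. Without the 2 libraries these counts were 2408 and 2319, and with exchanged labels 3082 and 2713. Between SD6 and SD3 edgeR called 0 genes as labelled (504 at an unadjusted p below 0.05; DESeq2 3), 2095 without the 2 libraries and 3040 with exchanged labels, and the strain count as a whole was 3645 and 4580.

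Whether the diet effect differed between strains was tested with 2 interaction terms. Nepl14, Nepl13, which encode proteases of the neprilysin family, Prx6c, Cpr64Ac, Fmo-1 and Fbp2 had the smallest p-values, all at an edgeR adjusted p of 0.977, and 0 genes passed as labelled (245 at an unadjusted p below 0.05; DESeq2 3). With the 2 libraries left out 6 genes passed, Fbp1, Fbp2, DptA, AttB, CG8665 and CG13075, and with exchanged labels Fbp1. The former fit has 1 LPS sample, a female one, in each of SD3 and SD6, and the lone sample is assumed to vary like the other groups. For the sex effect the smallest p-values were those of Cyp309a1, the inositol oxygenase gene Miox, Lcp65Ac, RNaseMRP:RNA, r-l and Proc-R, at an edgeR adjusted p of 0.846. As labelled 0 genes passed (478 at an unadjusted p below 0.05; DESeq2 1), against 0 without the 2 libraries, where SD3 and SD6 have 1 male each, and 6 with exchanged labels.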

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

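The tests of the strain labels, of the fat body lists, of the ratios between storage protein transcripts and of the tissue share in male pools, and the regroupings of paired samples for gene lists and of whole vial sets, were chosen only after the result was seen. So was every fit without the 2 libraries or with exchanged labels, on which the tests of the sequencing run and the regroupings with those fits rest. The other regroupings of the samples as labelled were planned.

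The library labelled male LPS SD3 resembled SD6 and the library labelled male LPS SD6 resembled SD3. Of the genes compared here, 9 were high in 1 of SD3 and SD6 and near absent in the other, 6 high in SD3 and 3 in SD6. High means at least 5 CPM in each sample of the strain, the 2 libraries left out. Near absent means under 0.05 of that strain's mean in each sample of the other. Some stayed above the floor in the other strain, such as Obp99a at 1.57 CPM in SD3 and mth at 1.71 CPM in SD6. RNA of both strains mixed in each library is argued against by these few genes. Those of the labelled strain stood at a median share of 0.0197 of its level in the library where that median was higher. A diet response of males that differs between strains is argued against by them too. In the library labelled male LPS SD3 0 of the 9 kept the labelled strain's state, and in the library labelled male LPS SD6 1 was counted as doing so. That gene, HHEX, stood at 2.08 CPM there, against 6.34 CPM in SD3 and 0.0134 CPM in SD6. It was counted for lying well under the SD3 level, and was not as low as in SD6. That is 5.56% of the gene states over both libraries. An exchange of the 2 strain labels may explain the pattern: on the 397 marker genes both libraries lay at least 0.973 of the way to the other strain. Where such an exchange would have happened and whether the diet labels hold was not tested, and the markers were picked from the other samples of the same series.

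Larval storage protein transcripts were lower on LPS, with Lsp2 at 101 CPM on HPS and 46.5 CPM on LPS over all samples. The sequencing run of the SD2 males is argued against as the whole cause, since the list's median was −1.75 without SD2 males and without the 2 libraries, a fit whose LPS samples are 3 females. Less fat body of any kind in the LPS pools is argued against, since the adult fat body list, which holds the yolk protein genes that vary between the sexes, had a median of 0.18 by diet without the 2 libraries. Less larval fat body left in the LPS pools, as the whole cause and with no other source of these transcripts, needs the members to fall alike. In ratios within samples 4 of 6 members moved apart without the 2 libraries, Fbp1 and Fbp2 falling more and Lsp1beta and Lsp1gamma less than the others (t-test, adjusted p = 0.0491 for each). With exchanged labels 5 did so and as labelled 0. Each ratio is taken against the other members, so a larger fall of some makes others fall less, and the 4 are not separate results. The fall of Fbp1 in females was −4.79 in SD2, −1.48 in SD3 and −2.02 in SD6. The ratios therefore do not decide the point. Less larval fat body, as the whole or a part of the cause, and an effect of larval diet on transcript per cell stay open. A difference in the hours since eclosion within the 2 to 6 h window was not tested.

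The muscle, adult fat body and haemocyte lists had negative medians and the nervous system lists positive ones in males, with myosin heavy chain Mhc at 6281 CPM in females and 4293 CPM in males. With an estimated correlation the muscle (adjusted p = 0.273), transmitter (0.293) and neuropeptide (0.229) lists were not called, and 3 of the 4 fat body genes that passed are yolk protein genes. The sequencing run of the SD2 males is argued against as the whole cause, since the muscle median was −0.26 without them, with strain labels exchanged. A smaller share of tissue other than nervous system in the male pools may explain the pattern, but the lists at hand cannot decide it. With exchanged labels the glia list, also of the nervous system, had a median of 0.08 with 15 of 18 members positive. As labelled camera did not call glia by sex. Phototransduction had 0.11 with 25 of 28, but it was among the positive lists that made up the pattern, so its sign is no separate support. A difference between the sexes within each tissue stays open and was not tested.

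Of the groups of pairs or samples tested, 0 of 7 by diet, 5 of 62 by sex and 2 of 18 by strain had 1 value far from the rest, where chance gives about 1 in 20. For the difference between male and female the ratio of the gap to the range was 0.745 for Yp1 (−8.30 in LPS SD6 against −9.35 to −9.09), 0.654 for Gcna (2.98 in HPS SD3 against 1.10 to 1.75) and 0.709 for Dh31 (0.67 in HPS SD2 against 0.28 to 0.39). It was 0.627 for t (0.06 in LPS SD6 against 0.43 to 0.65) and 0.669 for Ccp84Ab (0.10 in HPS SD3 against −1.09 to −0.69). The male of the LPS SD6 pair is a library of doubtful strain. Among SD2 samples Kaz1-ORFB had a ratio of 1 at the floor (−2.42 log2 CPM in the female HPS sample against −2.97), and among SD3 samples be had 0.851 (5.27 in the female HPS sample against 5.36 to 5.37).

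The diet effect differed between strains for 6 genes without the 2 libraries, in edgeR's interaction test. In this fit SD3 and SD6 have 1 LPS sample each, a female one that is assumed to vary like the other groups, and as labelled 0 genes passed. Fbp1 had an adjusted p of 0.00667, and 0.002 with exchanged labels (range over the fits 0.002 to 1). Its log2 differences by diet were −4.79 and −4.30 in females and males of SD2, −1.48 in SD3 females and −2.02 in SD6 females. Fbp2 had 0.00944 (0.00944 to 0.977), with −5.26 and −4.57 in SD2, −2.29 in SD3 females and −1.73 in SD6 females. The antibacterial peptide genes DptA (0.02, range 0.02 to 1) and AttB (0.0315, range 0.0315 to 1), CG13075 (0.02, range 0.02 to 1) and CG8665 (0.0381, range 0.0381 to 0.977) made up the rest. DptA was at 3.86 and 4.36 in SD2 and 0.31 and −0.20 in SD3 and SD6 females. In the test of the sex effect between strains 6 genes passed with exchanged labels, at 0.0411 for Jhbp3, the prophenoloxidase gene PPO1, CG11550 and CG3088, 0.044 for Yp2 and 0.0448 for CG7829, and the adjusted p of each ran up to 1 in the other fits compared. DESeq2 as labelled called 1 gene in this test, and edgeR 4 without the HPS SD6 male, which leaves 1 SD6 male.

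Both libraries of the smaller run had at least 5359 spike-in reads for each M gene reads, against 580 to 1442 in the other run, and at least 10.4% of their reads on no gene, against 2.93% to 4.96%.

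Regrouping the samples gave as many genes by diet as labelled in 3 of 100 splits (10, highest other 105), by sex in 2 of 100 (305, highest other 623) and by strain in 1 of 100 (922, highest other 753). The real split is counted in each. A count as high as that by sex was thus rare among the regroupings, though 1 of them gave more. Males and females of a strain and diet shared vials, which these splits ignore for diet and strain, and with the sexes summed 0 genes passed by diet as labelled. Splits that keep the 6 vial sets whole number 10 by diet and 15 by strain, too few for a share under 0.05. They gave as many by diet in 1 of 10 as labelled (10; 0), without the 2 libraries (147; 11) and with exchanged labels (170; 7), and by strain in 2 of 15 (922; 957, a split that kept SD2 together). The splits with 105 and 623 genes put the library labelled male LPS SD6 with SD3 samples and so point to the strain structure of the samples. Without the 2 libraries the real split alone reached its count by diet (1 of 100; 147; highest other 37) and by sex (1 of 99; 801; 173). Among the 32 splits that part all 6 pairs the real one alone did so by sex (1; 305; 0), and by diet (1; 10; highest other 0) and by diet with exchanged labels (1; 170; 5) if the sexes of a vial set count as separate samples. For diet in females (10 of 10; 0; 0), diet in males (10 of 10; 0; 3) and the diet by sex interaction with females (10 of 10; 0; 0) or males regrouped (10 of 10; 0; 1), the 10 splits are too few for a share under 0.05. For gene lists chance cannot be excluded: 12 of 100 splits gave as many by diet (14; 17) and 7 of 100 by sex (19; 23). Among the 32 splits that part all 6 pairs 5 did so by diet (14; 16) and 4 by sex (19; 20).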

How the results depend on the processing

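The fits without the 2 libraries of doubtful strain, with their strain labels exchanged, or with either of these combined with another choice, were chosen after seeing the data; the other alternatives were planned. The cause of a changed count was not tested, except that fewer samples were fitted where samples are left out. Of the genes called by diet, 10 as labelled, DESeq2 gave 111, limma-voom with strain as a random effect 1, the fit without the replicate block 0, the block by strain and sex 3, the sexes summed within the block 0 and the fit without SD2 males 0. Without the 2 libraries 147 genes were called, and 54 when the SD2 males were left out as well. With exchanged labels 170 were called, 148 and 170 with either library of the male LPS SD2 RNA alone, 364 with DESeq2 and 120 with the sexes summed. The scalings by RLE and upper quartile, the filters, robust dispersion, either library alone and all 13 libraries with run gave 8 to 14. For diet in females DESeq2 gave 23, the fit without the 2 libraries 54 and exchanged labels 28, against 0; in males DESeq2 gave 19 and exchanged labels 12, against 0. The diet by sex interaction stayed at 0 in edgeR, DESeq2 and limma-voom.

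By sex, 305 as labelled, DESeq2 gave 601, the fit without the replicate block 153, the block by strain and diet 190, the fit without SD2 males 40, the fit without the 2 libraries 801 and exchanged labels 1127. Between strains, 922 as labelled, DESeq2 gave 1479, all 13 libraries with run 581, the fit without SD2 males 87, the fit without the 2 libraries 3645 and exchanged labels 4580. The diet by strain interaction gave 3 genes with DESeq2, 6 without the 2 libraries and 1 with exchanged labels, and the sex by strain interaction 1 with DESeq2 and 6 with exchanged labels, each against 0. Camera with an estimated correlation called 0 lists by diet and 3 by sex and fry 4 and 12, against 14 and 19.

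Where an omission leaves 1 sample in an arm, as for the interactions with strain, that sample is assumed to vary like the other groups. Leaving out 1 sample or 1 strain gave 0 to 83 genes by diet, 14 to 559 by sex, 0 to 2281 between strains, and 0 to 10 by diet in females. It gave 0 to 28 in males, 0 to 0 for the interactions of diet with sex and with strain, and 0 to 4 for sex by strain. Lists were not run with single samples left out; leaving out 1 strain gave 12 to 13 by diet and 12 to 23 by sex, 12 being without strain SD6. By diet the count was 0 without the HPS SD2 male, the HPS SD2 female, the HPS SD6 female, the LPS SD2 female or the LPS SD3 female. It was 1 without the LPS SD6 female, 2 without either HPS SD3 sample, 3 without the LPS SD2 male and 6 without the HPS SD6 male. It was 25 and 83 without the libraries labelled male LPS SD3 and SD6. Those 2 omissions gave 1 and 10 by diet in females, 2 and 28 in males, 500 and 559 by sex and 1950 and 2281 between strains. By sex each other omission but that of the HPS SD6 male (232) left 140 to 199. For HPS it left 154 and 199 without the SD2 and SD3 males and 140, 194 and 168 without the SD2, SD3 and SD6 females. For LPS it left 158 without the SD2 male and 168, 165 and 182 without the SD2, SD3 and SD6 females. Between strains the omission of an SD2 sample left 450 (male HPS), 500 (female HPS), 394 (male LPS) and 479 (female LPS), and sex by strain rose to 4 without the HPS SD6 male. No named gene called by diet or sex changed direction. Of 252 values for 7 genes called by diet 112 lost the call, and of 1858 for 62 called by sex 384 did. Of 2663 and 1917 values for uncalled named genes 265 and 180 gained one. Scaling moved the median of all genes by little, with medians of 0.0059 to 0.010 by diet and 0.0079 to 0.014 by sex. Genes under the floor of 3 reads per library are not detectable at this depth.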

Other observations

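The comparison of chromosome arms within complexes was chosen only after the result was seen. In the proteasome all 4 X-linked subunits tested, Rpt3, Rpt4, Rpt6 and Prosalpha4, were lower in males and called in edgeR, with a median of −0.37. Of the 29 autosomal subunits 0 were called in edgeR, 6 were negative and the median was 0.045. Of the cytosolic ribosomal proteins 10 of 14 X-linked and 63 of 65 autosomal members were negative. The counts were 4 of 11 and 46 of 59 for mitochondrial ribosomal proteins and 7 of 11 and 50 of 57 for oxidative phosphorylation. Since the arms were compared because the called subunits were seen to be X-linked, these are given as values without a test.

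Genes high in 1 of SD3 and SD6 and near absent in the other included bgcn, at 0.245 CPM in SD3 and 24.4 CPM in SD6. CG12911 was at 25.0 CPM in SD3 and 0.0695 CPM in SD6. Both are over the samples whose strain is not in doubt. In the library labelled male LPS SD3 they stood at 24.9 and 0.111 CPM, and in the library labelled male LPS SD6 at 0.347 and 18.6 CPM.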
